A study of Mus musculus with 6 samples.

How the data were processed

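Single-cell RNA-seq was made from the ascending aorta of Myh11-CreERT2+ mT/mG mice in 6 groups, saline, AngII without IMH/D and AngII with IMH/D, each sorted into GFP+ and RFP+ cells. Each group is 1 library from a pool of 3 mice, and no map from cells to mice is among the sources used here. Per the labels' protocols, tissue was digested with enzymes, live single cells were sorted by flow cytometry, and libraries were made with the 10x Chromium 3′ v3 kit for a target of 10000 cells each. The saline GFP+ count matrix holds raw UMI counts per gene and cell as deposited, the filtered output of Cell Ranger on mm10 per the submitters' processing notes. The Cell Ranger version and whether intronic reads were counted are not given in the sources used here. The feature table lists 32285 genes, is the same in all 6 libraries and has no feature for GFP, tomato or Cre, so the sorted reporter could not be checked in the counts. Barcode lists of all 6 libraries were used, and of the expression data the saline GFP+ matrix only. Comparisons of expression between groups that were planned for libraries with a matrix could not be made.

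All choices in this and the next 2 paragraphs were made before the data were examined, except where stated. Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. Of 9338 barcodes, 910 were over the mitochondrial limit, 291 under the gene limit and 208 under the UMI limit, and 925 failed at least 1 of these. Scrublet, as built into scanpy 1.11.5, ran with an expected rate of 0.08 and marked 1 of 8413 cells or 0.0119%, under the minimum of 0.5% below which a caller was taken not to have worked. No cell was therefore removed as a doublet, and an alternative left out the 8% of cells with the highest doublet scores. The counts of each cell were split at random into 2 parts (binomial, 0.5, seed 0). Clusters came from the first part, with counts scaled to 10000 per cell and log-transformed, 2000 highly variable genes, 30 principal components, 15 exact nearest neighbours and Leiden clustering at resolution 0.5. Values per cluster came from the second part. Values over all SMC-like cells used all counts.

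Clusters were named from 17 marker sets fixed beforehand. The scoring was set after the clusters were seen. A cluster was SMC-like when its median SMC marker ratio to all cells was at least 0.5 and fewer than 3 markers of another class stood at 50 CPM or more and 5-fold above the other cells (on CPM + 1), was named for another class when at least 3 such markers were found and the SMC ratio was lower, and otherwise stayed unnamed. A 3-fold limit in place of 5-fold left every share of these classes as it was. SMC-like cells were clustered again without the 362 genes of the fixed lists and marker sets, mitochondrial genes or ribosomal protein genes, keeping subclusters of at least 50 cells. For 22 gene lists fixed beforehand, the level was the summed CPM, and the ratio in a subcluster was taken over all other SMC-like cells. Members were counted among those at 20 CPM or more in SMC-like cells, as at least 25% higher or at least 20% lower, sizes set after the subclusters were seen. Of the lists, 1 member of the unfolded protein response list (Ddit3) and 2 of the interferon list were not in the feature table by symbol.

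The genes named are, for each list, the 2 to 4 members with the highest level in SMC-like cells and the members with the highest and lowest ratio in a described subcluster, the 20 most variable genes at 50 CPM or more, the 5 leading genes of each cluster, to say what it is, and Myh11, Acta2, Agtr1a, Agtr1b, Agtr2, Klf4, Tgfbr1, Tgfbr2, Fbn1 and Eln. Spp1, Myl9, Mfap5, Tnfrsf11b, Nr4a3, C1qa, C1qb, Ccl2, Lyz2, Mrc1, Vcam1, Neat1, the remaining pericyte markers, the fibroblast and cardiomyocyte markers given for cluster 3, Dlx5 and Dlx6 were added after their values were seen. Correlations are Spearman's, between summed UMIs of lists in cells thinned to 2000 UMIs, with genes shared by both lists taken out. Each has its percentile among 1000 random lists whose genes lay within 50 ranks of the list's genes in mean expression. Of the SMC-like cells, 17 were too shallow for thinning. The variance over the mean of thinned counts was divided by the running median over 100 genes of like level. At the ends of the ranking the window was cut short, so the most abundant genes were set mostly against less abundant ones. These windows were set after the counts were seen. Exact Poisson and Clopper-Pearson 95% intervals and the limit of 3 counts cover counting error only. Gene positions come from GENCODE release M21 (GRCm38, the build also called mm10), which held 32158 of the 32285 gene identifiers, or 99.6%.

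A test of free RNA in cluster 6 by the share of positive cells was left out because it restated the signal, and a test of doublets in subcluster 5 by depth and doublet score because the caller had not worked. A test of nuclear RNA in subcluster 2 by the median of the contractile members was replaced by one on their sum, since they went both ways. The tests that replaced these, and their limits, were set with the values known. Matched draws took each member's ratio from the 50 genes nearest in level and gene length, 10000 times, and were read by median and by sum, each member at its own level.

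The steps were tested on simulated data. Counts of 3000 cells were drawn for 32285 genes from the real means and depths, with no change or with 200 genes changed by 2-fold or 4-fold in 180 cells. In those cells the elastic fibre list was raised and the contractile list lowered as well. With no change, 30 list ratios, of the more abundant lists, lay between 0.988 and 1.01. Genes were drawn independently of each other, so the lists could not vary with the clustering features as they can in real cells. These ratios therefore cover counting noise only. With change, the changed cells were found at a Jaccard index of 0.989, an elastic fibre ratio drawn at 1.97 over 17 genes came out as 1.96, and a contractile ratio drawn at 0.592 over 20 genes as 0.588. The variable-gene step gave no relative variance over 1.10 among 3203 genes with no change, and 64.5% of 62 genes changed 4-fold ranked among its 200 highest. The alternatives varied the filters on cells, the treatment of doublets, the clustering resolution, the number of variable genes, the split of the counts, the features, the thinning depth, the cells included and the denominator of CPM. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9.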

Results

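The series measured single-cell transcriptomes of the mouse ascending aorta in 6 libraries, 1 per group, each made from a pool of 3 mice. The mice carried a tamoxifen-inducible Cre under the smooth muscle myosin gene Myh11 and a double-colour membrane reporter, so that smooth muscle cells (SMCs) and their descendants became GFP+ and other cells stayed RFP+. Tamoxifen was given at week 6. From week 9 the mice received saline or AngII, the pressor peptide angiotensin II, for 7 days, AngII at a dose of 1000 ng/kg/min. AngII aortas were divided by the absence or presence of intramural hematoma or dissection (IMH/D), and GFP+ and RFP+ cells were sorted into separate libraries. The study asks how SMCs change while aortic aneurysm and dissection develop.

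The gene expression of 1 library, saline GFP+, is described here. Counts of the other 5 libraries were not analysed here, so no difference in expression between AngII and saline, between aortas with and without IMH/D, or between GFP+ and RFP+ cells is given. With 1 library per group and cells that are not replicates of each other, no test between groups was run and no p-value is given. Intervals on counts are exact Poisson intervals and intervals on shares are exact Clopper-Pearson intervals, both at 95%. They cover counting error only, not differences between mice or between preparations.

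The number of cell barcodes differed between the groups. The saline libraries held 9338 GFP+ and 12957 RFP+ barcodes. Without IMH/D, the AngII libraries held 18392 GFP+ and 27446 RFP+ barcodes. With IMH/D, they held 28495 GFP+ and 15395 RFP+ barcodes, so that GFP+ barcodes outnumbered RFP+ barcodes in this condition and not in the other conditions. Each library was loaded for a target of 10000 cells, and the sort, the loading and the calling of cells set these numbers, so they do not measure the share of SMCs in the tissue. The 15 pairs of libraries shared 29 to 235 barcode sequences. Per 1000000 possible pairs of barcodes this was 0.215 to 0.319 with a median of 0.263, so no pair stood out as sharing a duplicated barcode list. A swap of whole lists between libraries would not show in these values.

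The saline GFP+ library held 157209944 unique molecular identifiers (UMIs) in 9338 barcodes, with a median of 16362 UMIs and 4277 genes per barcode. After barcodes with few genes, few UMIs or a high mitochondrial share were removed, 8413 cells with 154228229 UMIs remained. Their median was 17042 UMIs, 4366 genes and 3.93% mitochondrial UMIs, and the 5th to 95th percentile range was 10021 to 31901 UMIs. The 925 barcodes removed had a median of 2603 UMIs, of which 25.5% were mitochondrial.

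SMC-like cells made up nearly the whole library, at 8164 of 8413 cells or 97.0% (96.7 to 97.4%). They carried the smooth muscle actin Acta2 at 23551 counts per 1000000 (CPM), the actin-binding protein transgelin, Tagln, at 15185 CPM and Myh11 at 3804 CPM. Fibroblast-like cells numbered 72, or 0.856% (0.670 to 1.08%), with 12092 CPM of the small proteoglycan decorin (Dcn) against 104 CPM in SMC-like cells, 2203 against 37.1 CPM of lumican (Lum), and 803 CPM of Myh11. Proliferating cell-like cells numbered 63, or 0.749% (0.576 to 0.957%). In them the proliferation marker Mki67 stood at 141 CPM, the topoisomerase Top2a at 136 CPM and Myh11 at 1349 CPM, and their median depth was 27732 UMIs. None of the 14 other classes sought, among them endothelial, macrophage, neutrophil, T cell, pericyte and mesothelial cells, was found as a cluster. This does not exclude them, since cells of a rare class can lie within another cluster. A pair of clusters stayed unnamed under a naming rule set after the clusters were seen, cluster 6 with 1.13% and cluster 9 with 0.226% of cells. The share of SMC-like cells ranged from 89.4 to 99.0% over other settings. The small classes were less stable, with the fibroblast-like share between 0 and 0.880% and the proliferating share between 0 and 1.15%, because these cells then joined larger clusters. The gate for GFP+ cells sets these shares.

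**Figure D1:**
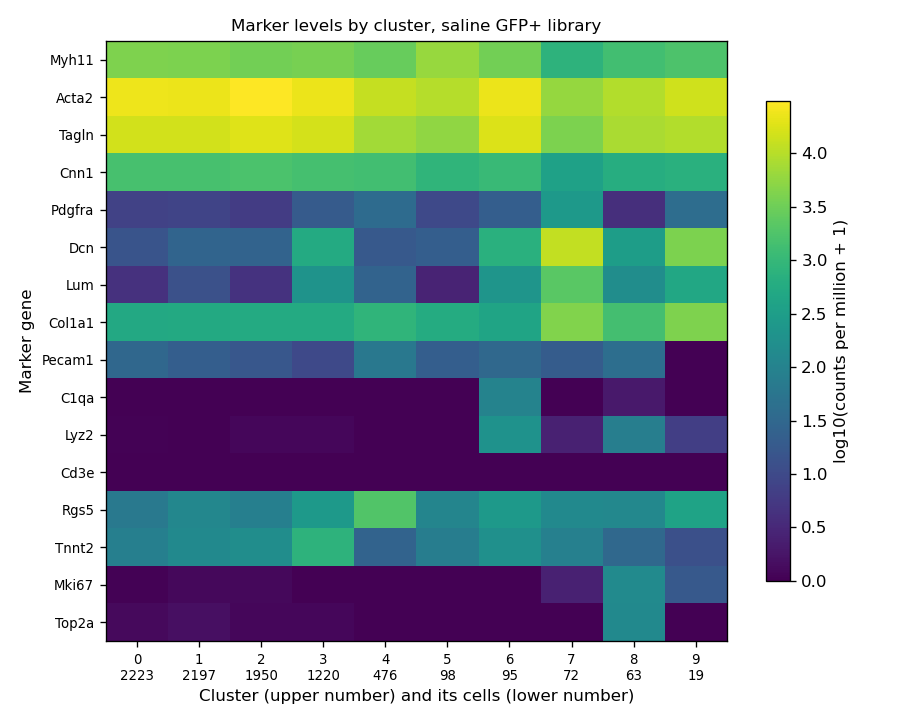
Levels of 16 marker genes (vertical axis) in the 10 clusters of the saline GFP+ library (horizontal axis, with the number of cells of each), as colour on a scale of log10(CPM + 1). Clusters 0 to 5 are SMC-like and carry Myh11 at 2777 to 6160 CPM, cluster 7 is fibroblast-like with Dcn at 12092 CPM and cluster 8 is proliferating cell-like with Mki67 at 141 CPM.

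The 6 SMC-like clusters were led by different genes. Cluster 0, with 2223 cells, was led by Carmn, Acan, Cdh6, Fabp4 and Epas1. Cluster 1, with 2197 cells, was led by Gm17056, Lsmem1, Egr3, Flnc and Arc. Cluster 2, with 1950 cells, was led by Gm13889, Spint2, Csrp1, Tbxa2r and Ppp1r14a. Cluster 3, with 1220 cells, was led by Tnnt2, Psd, Lum, Cp and Igf1. Its 10 leading genes thus held the fibroblast markers Lum at 5.67-fold and Dcn at 3.49-fold and the cardiomyocyte marker Tnnt2 at 6.92-fold. They held 1 SMC marker, Des, so these 10 genes point more to other classes. The rest of both marker sets did so less. Pdgfra, Dpt and Cd34 were also above their levels in all SMC-like cells, at 18.0, 21.6 and 27.7 CPM. Col1a1, Col1a2 and Gsn were not, at 553, 1310 and 592 against 551, 1423 and 649 CPM. Of the other cardiomyocyte markers, Actn2 stood at 65.9 against 63.7 CPM and none of the rest above 2.39 CPM. The cluster's name rests on a median SMC marker ratio to all cells of 0.983, with Myh11 at 3708 CPM. Cluster 4, with 476 cells, was led by Adamtsl1, Mdga2, Fgf12, Ralyl and Prss12. Cluster 5, with 98 cells, was led by Lars2, Zfp385a, Neat1, March3 and Ints6 and had a lower median depth of 8830 UMIs and a higher mitochondrial share of 6.84%. Fibroblast-like cluster 7 was led by Clec3b, Cygb, Svep1, Dpep1 and Abca8a. Proliferating cluster 8 was led by Retnla, Mki67, Top2a, Cenpf and Hmmr, of which Retnla is an immune-associated gene.

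Contractile genes had the highest summed level of the 22 lists in the 8164 SMC-like cells. The 20 contractile genes together took 77216 CPM (77172 to 77261), each member was at 20 CPM or more, and 13 were at 1000 CPM or more. Acta2 was the most abundant gene of all at 23543 CPM, followed within the list by Tagln at 15177 CPM, the myosin light chain Myl6 at 8656 CPM and the tropomyosin Tpm2 at 5330 CPM. Regulators of the SMC programme were far less abundant, with 1957 CPM over 18 genes. The shear-responsive factor Klf2 led them at 421 CPM, before the coactivator of serum response factor Myocd at 358 CPM, Mef2c at 298 CPM and Klf4 at 261 CPM. Ion channel and calcium-handling genes reached 1961 CPM over 19 genes, led by the sarcoplasmic calcium pump Atp2a2 at 553 CPM, the large-conductance potassium channel Kcnma1 at 268 CPM and the inositol trisphosphate receptor Itpr1 at 238 CPM. Receptors and effectors of vascular tone reached 1338 CPM over 18 genes. These were mostly parts of the nitric oxide pathway, the cGMP-dependent kinase Prkg1 at 634 CPM and the guanylate cyclase subunits Gucy1a1 at 284 CPM and Gucy1b1 at 258 CPM.

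Extracellular matrix genes formed the next large group. The 23 proteoglycan and matricellular genes took 18678 CPM (18656 to 18700), led by the calcification inhibitor Mgp at 5838 CPM, Sparc at 3005 CPM, biglycan (Bgn) at 2822 CPM and Ccn2 at 1384 CPM. The 17 elastic fibre genes took 7092 CPM (7078 to 7105), led by elastin (Eln) at 2405 CPM, the elastic fibre assembly protein Fbln5 at 991 CPM, the latent TGF-beta binding protein Ltbp1 at 835 CPM and Mfap4 at 758 CPM. The 16 collagens took 6175 CPM (6163 to 6188), with Col1a2 at 1423 CPM, Col3a1 at 1166 CPM and the basement membrane collagen Col18a1 at 945 CPM. Proteases and their inhibitors took 4213 CPM over 24 genes, and inhibitors led them, namely the metalloproteinase inhibitors Timp3 at 971 CPM and Timp2 at 448 CPM and the serpin Serpine2 at 775 CPM. Genes of the heritable thoracic aortic disease list took 36906 CPM over 22 genes, 18 of them at 20 CPM or more, and this list shares Acta2, Myh11, Bgn and the filamin Flna with the groups above or with the contractile list.

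Genes of modulated SMCs, those that rise when SMCs lose their contractile state, contributed 1359 CPM over 18 genes, 8 of them at 20 CPM or more. Fibronectin (Fn1) at 512 CPM and S100a4 at 502 CPM made up most of this, while Dcn stood at 104 CPM, Lgals3 at 57.1 CPM and the osteogenic marker Spp1 at 1.07 CPM. Chemokine and inflammation genes took 382 CPM over 20 genes, and 4 of these were at or under the level of 3 UMIs. The inhibitor of NF-kappa-B Nfkbia led them at 137 CPM, before Cxcl12 at 76.1 CPM. Interferon response genes took 874 CPM over 16 genes, led by the antigen presentation genes B2m at 388 CPM and H2-D1 at 211 CPM. Cell cycle genes took 190 CPM over 17 genes, of which the cell cycle inhibitor Cdkn1a held 129 CPM and Pcna 45.3 CPM. Cell death genes took 636 CPM over 16 genes, led by the survival factor Mcl1 at 182 CPM and the apoptosis effector Bax at 102 CPM.

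Stress and signalling genes ranged widely. Immediate-early genes, which enzymatic dissociation also induces, took 16801 CPM (16780 to 16822) over 17 genes, with the transcription factors Fos at 4286 CPM, Egr1 at 1471 CPM and Jund at 1358 CPM and the antiproliferative gene Btg2 at 1773 CPM. Heat shock genes took 4558 CPM over 11 genes, led by Hspb1 at 1378 CPM and Hspa8 at 1351 CPM. Genes of the unfolded protein response took 1995 CPM over 11 genes, led by the endoplasmic reticulum chaperones Hsp90b1 at 481 CPM, Calr at 453 CPM and Hspa5 at 435 CPM. TGF-beta and BMP signalling genes took 3024 CPM over 20 genes, with the BMP target genes Id3 at 967 CPM, Id2 at 374 CPM and Id1 at 293 CPM and the ligand Tgfb2 at 171 CPM. Notch genes took 469 CPM over 11 genes, led by the target genes Heyl at 132 CPM and Hes1 at 112 CPM. Nuclear genes of mitochondrial respiration took 3985 CPM over 16 genes, led by Cox4i1 at 993 CPM and Cox6c at 692 CPM. Positional transcription factors took 733 CPM over 26 genes, led by Gata6 at 153 CPM, Foxc1 at 116 CPM and Hand2 at 87.8 CPM.

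The angiotensin pathway list took 993 CPM over 15 genes, of which the NADPH oxidase Nox4 held 447 CPM and the regulators of G protein signalling Rgs5 and Rgs4 held 214 and 98.1 CPM. The receptors themselves were scarce. Agtr1a (ENSMUSG00000049115, chromosome 13, 30336441 to 30382867, mm10) gave 286 UMIs or 1.92 CPM (1.70 to 2.15). Cells with an Agtr1a UMI made up 3.25% of SMC-like cells at a median of 17025 UMIs and 4.17% of fibroblast-like cells at a median of 15857 UMIs, and 0.454 and 0% after every cell was thinned to 2000 UMIs. The SMC-like share was the lower of the pair before thinning and the higher after it, with only 72 fibroblast-like cells to compare. No class here is known to lack the gene, so a subset of SMCs with the receptor cannot be read from these shares. Agtr1b (ENSMUSG00000054988, chromosome 3, 20314473 to 20367177) gave 73 UMIs or 0.490 CPM (0.384 to 0.616), in 0.551% of SMC-like and 2.78% of fibroblast-like cells, or 0.0860 and 0% after thinning. Agtr2 (ENSMUSG00000068122, chromosome X, 21484544 to 21489164) gave 0 of 149106657 UMIs. The limit of 3 counts then stands at 0.0201 CPM, and the upper end of the Poisson interval at 0.025 CPM.

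The other genes of interest in aortic disease were well measured. Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590, mm10) stood at 23543 CPM (23518 to 23567), and Myh11 (ENSMUSG00000018830, chromosome 16, 14194535 to 14291372) at 3801 CPM (3791 to 3811). A Myh11 UMI was seen in 99.95% of SMC-like and 58.3% of fibroblast-like cells, and in 98.7 and 38.9% after thinning to 2000 UMIs. Eln (ENSMUSG00000029675, chromosome 5, 134702593 to 134747323) stood at 2405 CPM (2398 to 2413), and the microfibril gene Fbn1 (ENSMUSG00000027204, chromosome 2, 125300594 to 125507993) at 187 CPM (185 to 189). The TGF-beta receptors Tgfbr1 (ENSMUSG00000007613, chromosome 4, 47353222 to 47414931) and Tgfbr2 (ENSMUSG00000032440, chromosome 9, 116084293 to 116175360) stood at 154 CPM (152 to 156) and 66.6 CPM (65.3 to 67.9). Klf4 (ENSMUSG00000003032, chromosome 4, 55527143 to 55532466), a factor linked to SMC dedifferentiation, stood at 261 CPM (258 to 263).

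Within the SMC-like cells, groups of cells were sought without the genes of the fixed lists, and the lists were then read in each group. Cells were not assigned to the 3 mice, so the share of each mouse in a subcluster is unknown. Subcluster 5, with 476 cells or 5.83% (5.33 to 6.36%), was the most distinct. Its elastic fibre genes stood 2.11-fold higher than in the other SMC-like cells (2.09 to 2.13), at 14075 against 6676 CPM, and 11 of 13 measured members were at least 25% higher. Eln was 2.22-fold higher at 4999 CPM, Fbln5 2.71-fold, the microfibril protein Mfap5 3.66-fold and fibulin-1 (Fbln1) 11.8-fold, whereas Emilin1 was lower at 0.766-fold. Contractile genes were lower at 0.624-fold (0.622 to 0.627), with 12 of 20 members at least 20% lower. Acta2 was at 0.510-fold, Tagln at 0.476-fold and desmin (Des) at 0.0750-fold. Collagens were 1.45-fold higher with 8 of 13 members at least 25% higher, among them Col15a1 at 3.49-fold and Col1a2 at 1.95-fold, and Col18a1 was lower at 0.795-fold. Proteoglycan and matricellular genes did not rise as a group, at 0.937-fold. Of 17 members 10 were at least 20% lower, among them Mgp at 0.674-fold, Acan at 0.525-fold and Tnc lowest. A further 4 were at least 25% higher, among them Vcan at 4.17-fold and Sparc at 2.00-fold. Proteases and inhibitors were 1.34-fold higher, with the gelatinase Mmp2 at 3.98-fold, Timp3 at 1.64-fold and the aggrecanase Adamts5 at 0.293-fold.

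Signalling genes also set subcluster 5 apart. The angiotensin pathway list was 2.91-fold higher, which rested on Rgs5 at 1857 against 119 CPM, 15.6-fold, while Nox4 was at 0.827-fold. Rgs5 is also a marker of pericytes, and of the other pericyte markers the potassium channel subunits Kcnj8 and Abcc9 were 3.57-fold and 2.54-fold higher, Notch3 was lower at 0.460-fold, Cspg4 stood at 245 CPM in the matching cluster 4 against 249 CPM in all SMC-like cells, and Higd1b and Vtn had no UMI there. Notch genes were lower at 0.670-fold with 5 of 7 members at least 20% lower, among them Hey2 at 0.324-fold, Heyl at 0.435-fold and Hes1 at 0.557-fold, and Rbpj was at 1.29-fold. The TGF-beta and BMP list was 1.27-fold higher with 6 of 18 members at least 25% higher, among them endoglin (Eng) at 1.95-fold, Tgfbr1 at 1.68-fold and Id3 at 1.58-fold, and the inhibitory Smad7 was at 0.710-fold. Genes of the unfolded protein response were 1.41-fold higher with 6 of 9 members past that size, led by Hsp90b1 at 1.59-fold. The ratios in subcluster 5 also rose with gene length at a Spearman rho of 0.326, with a median log2 ratio of 0.33 in the longest 20% of genes. Against draws of genes matched on level and length, the TGF-beta and BMP list lay at percentile 93.7 by median and 99.3 by sum, collagens at 99.99 and 94.3, and proteases at 100 and 93.7. Gene length thus did not account for the typical rise of collagens and proteases, while it stays open for their summed levels and for the TGF-beta and BMP median. Among regulators, the chondrogenic factor Sox9 was 4.54-fold and Klf4 1.86-fold higher. Modulated SMC genes were not raised as a group at 0.886-fold, with 7 of 8 members at least 20% lower, Tnc lowest at 0.0650-fold, and Fn1 at 1.32-fold. With the 20 most abundant genes left out of the totals, the contractile ratio was 0.760, the elastic fibre ratio 2.01 and that of every other gene 0.953 of the value given. In that setting the heritable thoracic aortic disease list was at 0.955-fold instead of 0.685-fold, since Acta2 leaves it.

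**Figure D2:**
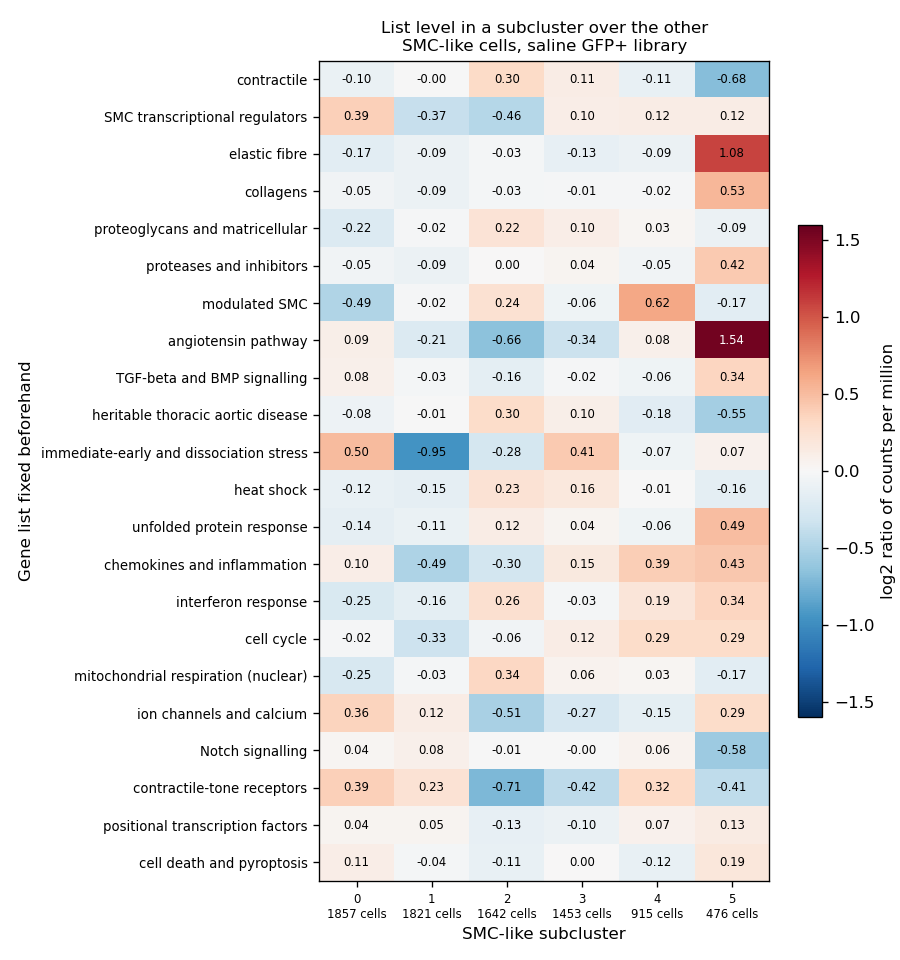
Levels of the 22 gene lists (vertical axis) in each of 6 subclusters of SMC-like cells (horizontal axis, with the number of cells of each) over the other SMC-like cells, as the log2 ratio of CPM in colour and in figures. Subcluster 5 stands out with an elastic fibre ratio of 2.11-fold and a contractile ratio of 0.624-fold, and subcluster 1 with an immediate-early ratio of 0.517-fold, while the contractile ratios of subclusters 0, 1, 2 and 3 change side when the 20 most abundant genes are left out, to 1.09-fold, 1.07-fold, 0.955-fold and 0.968-fold.

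Immediate-early genes divided the more numerous subclusters. In subcluster 1, with 1821 cells or 22.3%, the list was at 0.517-fold (0.514 to 0.520), and 14 of 15 measured members were at least 20% lower. Fos stood at 2491 against 4799 CPM, the cytokine signalling inhibitor Socs3 was at 0.242-fold and Klf6 at 0.878-fold, and outside this list Klf4 was at 0.362-fold. In subcluster 0, with 1857 cells or 22.7%, the list was 1.42-fold higher with 11 of 15 members at least 25% higher, among them Fosb at 2.08-fold and Btg2 at 1.70-fold. The nuclear RNAs Malat1 and Neat1 were also higher there, at 28104 against 18812 CPM and 305 against 92.8 CPM, and the median depth was 20123 against 16180 UMIs. In subcluster 3, with 1453 cells or 17.8%, it was 1.33-fold higher with 10 of 15 members at least 25% higher, among them Socs3 at 1.73-fold and Fos at 1.34-fold. Contractile genes differed little with these states, at 0.932-fold, 0.997-fold and 1.08-fold in subclusters 0, 1 and 3, and at 1.09-fold, 1.07-fold and 0.968-fold with the 20 most abundant genes left out. Immediate-early genes outside the fixed list were among the leading genes of these subclusters, Arc at rank 1 in subcluster 3 and Nr4a3 at rank 4 in subcluster 0, so the list was not independent of how these cells were grouped. At a lower clustering resolution of 0.3 the group nearest to subcluster 1 had an immediate-early ratio of 1.08 and overlapped it at a Jaccard index of 0.286.

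Subcluster 2, with 1642 cells or 20.1%, combined high contractile and respiratory transcripts with low transcripts of channels and regulators. Its contractile genes were 1.23-fold higher (1.23 to 1.24), with Csrp1 at 1.54-fold and Acta2 at 1.37-fold, but 8 of 20 members were at least 25% higher and 5 at least 20% lower. All 14 measured genes of mitochondrial respiration lay above 1, at 1.26-fold together, with the complex III subunit Uqcrc1 highest at 1.46-fold and Tfam lowest at 1.08-fold. Ion channel genes were at 0.701-fold with 7 of 12 members at least 20% lower, among them the stretch-activated channel Piezo2 at 0.289-fold. Tone receptors were at 0.610-fold, with Prkg1 at 0.306-fold and the thromboxane receptor Tbxa2r at 1.52-fold, and regulators were at 0.729-fold with Myocd at 0.413-fold. The ratio of genes to the other SMC-like cells also fell with gene length at a Spearman rho of -0.741, with a median log2 ratio of -0.77 in the longest 20% of genes, so low levels of long genes are not specific to these lists. Against genes matched on level and length, channels and tone receptors lay at percentiles 57.8 and 24.8 by median. Regulators lay at 0.330, so gene length did not account for their fall. The nuclear RNA Malat1 stood at 5758 against 24238 CPM in the other SMC-like cells, and the median depth was 13982 against 17847 UMIs. Leaving the 20 most abundant genes out turned the contractile ratio to 0.955, because Acta2, Tagln, Myl6, Tpm2 and Myl9 leave the list with them.

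Subcluster 4, with 915 cells or 11.2% (10.5 to 11.9%), carried fibroblast and modulated SMC transcripts at low levels. Modulated SMC genes were 1.53-fold higher, a value that rested on Lum at 27.0-fold, Dcn at 23.0-fold and the osteoprotegerin gene Tnfrsf11b at 3.41-fold, while Tnc was at 0.433-fold and Fn1 at 0.621-fold. Dcn stood at 675 CPM, far below the 12092 CPM of fibroblast-like cells. Contractile genes were near those of other cells at 0.924-fold, with Des highest at 2.59-fold and Csrp1 lowest at 0.814-fold. Among matrix genes Col14a1 was at 3.11-fold, Fbln1 at 3.66-fold and Eln at 0.727-fold. This grouping was not stable, and the nearest group had a modulated SMC ratio below 1, from 0.558 to 0.907, under 5 of 16 other settings. Of these 16 settings 1 was the main run itself, and the highest ratio among them was 2.51. The settings with a ratio below 1 left out cluster 3, or clusters made up mostly of its cells that stayed unnamed. Cluster 3 shares the leading genes Lum, Dcn, Tnnt2, Cp and Igf1 with subcluster 4. Those ratios thus come from a changed set of cells and do not test the rise in the cells of subcluster 4.

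Contractile genes varied with other groups of genes from cell to cell. Over 8147 SMC-like cells thinned to 2000 UMIs, contractile UMIs correlated with those of mitochondrial respiration genes at a Spearman rho of 0.220, above 99.6% of 1000 random lists of like expression. Over other settings this value ranged from 0.160 to 0.414. Heat shock genes correlated at 0.142, the percentile being 90.8. Negative correlations came from the angiotensin pathway at -0.219 and from proteases and inhibitors at -0.202, with percentiles of 0.1 and 0.4. Over other settings they ranged from -0.332 to -0.164 and from -0.304 to -0.149. In subcluster 5, where contractile genes were at 0.624-fold, the rise of the angiotensin list rested on Rgs5. The correlation without Rgs5 was not computed. In the main run the lowest value was that of heritable thoracic aortic disease genes at -0.240, with elastic fibre genes at -0.227, collagens at -0.192, modulated SMC genes at -0.185 and TGF-beta and BMP genes at -0.163, and percentiles of 1.9, 2.0, 1.0, 2.4 and 1.9. Immediate-early genes at -0.056, where random lists had a median of 0.109, and Notch genes at 0.001 lay within the range of such lists, with percentiles of 8.5 and 83.4. The lists correlated were stripped of shared genes, and cells within a library are not independent samples. Random lists were matched on mean expression only, not on gene length, with which the ratios in subclusters 2 and 5 changed.

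Dcn, Malat1 and Mgp varied most between SMC-like cells beyond counting noise. Relative to the genes nearest in level, the variance over the mean was 13.5 for Dcn, 10.8 for Malat1, 9.13 for Mgp, 7.39 for Adamtsl1 and 5.67 for the apolipoprotein Apoe. The most abundant genes, such as Malat1, Mgp and Acta2, had few genes of like level, so their values may be too high. Myh11, at rank 21 by level, stood at 3801 CPM against 21296 CPM for Malat1. Dcn reached 675 CPM in subcluster 4 and 11.9 to 71.1 CPM in the other subclusters. Adamtsl1, a secreted ADAMTS-like protein, reached 2032 CPM in subcluster 5 and 1.77 to 14.2 CPM elsewhere. Rgs5 at 5.18, Sfrp2, a secreted Wnt modulator, at 3.70, Eln at 3.30 and Kcnip4 at 2.96 were also highest in subcluster 5, and cardiac troponin T (Tnnt2) at 5.08, Igfbp2 at 4.57 and Des at 3.08 in subcluster 4. Acta2 itself stood at 3.96. The stress-responsive genes Klf2, Atf3, Fos and Junb ranged from 2.91 to 3.15, and Gm42418, Ftl1 and Tcap completed the 20 most variable genes. Of 3177 genes ranked, 56 had a relative variance over 2.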

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

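Of the tests in this part, those of free RNA and of doublets in cluster 6, with their limits, were set after the values were known. A pair of signals appeared in the unnamed clusters, which the comparisons of SMC-like cells do not use, above the limit that a count of 0 allows. In cluster 6, the complement gene C1qa of macrophages stood at 99.33 CPM (78.13 to 124.51), against a limit of 3.97 CPM, and 0 UMIs were seen in SMC-like cells. Its 75 UMIs came from 3 of 95 cells. In cluster 9, the monocyte chemoattractant Ccl2 stood at 1554.81 CPM (1376 to 1750), against a limit of 17.0 CPM and a level of 0.201 CPM in SMC-like cells. Its 274 UMIs came from 3 of 19 cells.

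The macrophage transcripts of cluster 6 were weighed further. Free RNA taken up by an SMC would leave its contractile level nearly whole, but that of the 2 cells with at least 2 C1qa or C1qb UMIs was 0.025 of that of SMC-like cells. Doublets of an SMC and a macrophage would carry contractile transcripts, but the highest level of these cells was 0.030. These cells could be macrophages that passed the GFP+ sort, since their contractile level of 1932 against 77216 CPM was 0.025, and the macrophage markers took 27798 CPM. No biological explanation was tested, since the design names no group within this library, and 2 cells do not set the identity of the other cells of the cluster. Summed over its 95 cells, cluster 6 had contractile genes at 1.014-fold of SMC-like cells (1.006 to 1.022) and a median SMC marker ratio of 0.904. Elastic fibre genes were at 0.523-fold and modulated SMC genes at 2.36-fold. The cluster as a whole was thus contractile, and it stayed unnamed because 3 macrophage markers passed the naming limit.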

How the results depend on the processing

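Chosen after the data were seen were the alternatives on the naming limit, on cluster 3, on subcluster 2, on thinning before clustering and on abundant genes in subclusters; the one on the highest doublet scores was named beforehand for the case that occurred. Over 17 results and 180 alternative values, 73 stayed within the counting interval or tolerance, 100 moved beyond it in the same direction and 7 reversed. For each of the 17 results, 1 of these values was the main run itself, since its setting was that no doublets were removed. These copies count among the 73 and say nothing on stability. No paired analysis was possible because each group is 1 library and no test between groups was run. The cause of the changes below was not tested unless stated.

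The SMC-like share was 98.966% with 1000 and 89.397% with 3000 variable genes, 97.896 and 92.381% at resolutions 0.3 and 1.0, 95.828% with all counts, 91.834% with another split, and 95.366, 95.598 and 93.352% with at least 1000 genes, at least 200 genes and up to 20% mitochondrial UMIs. The contractile level was 77074.4, 77503.6 and 76767.5 CPM under those 3 filters, 77467.5 CPM without cluster 3, and 23829.7 CPM without the 20 most abundant genes, which include Acta2 and Tagln. The correlation of contractile with respiration genes was 0.160 and 0.292 at 1000 and 5000 UMIs per cell, 0.414 with no thinning and 0.309 with up to 20% mitochondrial UMIs.

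The contractile ratio of subcluster 5 was 0.631 with 1000 and 0.619 with 3000 variable genes, 0.628 and 0.627 at resolutions 0.3 and 1.0, 0.628 with all counts, 0.619 with another split, 0.610 with at least 200 genes, 0.631 with up to 20% mitochondrial UMIs, 0.646 without subcluster 2, 0.605 at 5000 UMIs per cell, 0.760 without the 20 most abundant genes and 0.584 without the highest doublet scores. Its elastic fibre ratio was 2.069 at resolution 1.0, 2.153 with at least 200 genes, 2.147 with another split, 2.127 without cluster 3, 2.127 without subcluster 2, 2.237 at 5000 UMIs, 2.009 without the 20 most abundant genes and 2.209 without the highest doublet scores. The matching groups had a Jaccard index of at least 0.847. The list of the 20 most variable genes shared 18 to 20 genes over 4 alternatives, of which 1 was the main run itself.

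The contractile ratio of subcluster 2 reversed to 0.955 without the 20 most abundant genes, since 5 contractile genes leave the list with them. The immediate-early ratio of subcluster 1 reversed to 1.082 at resolution 0.3. The modulated SMC ratio of subcluster 4 reversed to 0.782 with 3000 variable genes, 0.558 at resolution 1.0, 0.845 with up to 20% mitochondrial UMIs, 0.784 without cluster 3 and 0.907 with another split, where the nearest group overlapped it at a Jaccard index of 0.262 or less. Cluster 3 shares leading genes with subcluster 4, so leaving it out takes like cells away beforehand. Under the rest, in the order given, clusters of 483, 448, 559 and 478 cells stayed unnamed and were not reclustered. Cells of cluster 3 made up 77.8, 84.2, 65.8 and 79.7% of them. With at least 1000 genes a cluster of 282 cells, 66.7% from cluster 3, also stayed unnamed, without a reversal. Depth limits the rarest genes most, since 0 of 149106657 UMIs for Agtr2 still allow 0.0201 CPM by the limit of 3 counts.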

Other observations

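The smaller clusters differed from SMC-like cells in several gene lists, which were read after these clusters were seen and whose genes could help to form them. In the 72 fibroblast-like cells, modulated SMC genes were 12.1-fold higher (11.9 to 12.4), collagens 3.09-fold, proteoglycan and matricellular genes 2.54-fold, chemokine and inflammation genes 4.85-fold and interferon response genes 2.35-fold higher, and contractile genes were at 0.278-fold. In the 63 proliferating cell-like cells, cell cycle genes were 6.07-fold higher (5.71 to 6.45), and so were chemokine and inflammation genes at 7.55-fold and modulated SMC genes at 6.94-fold. Contractile genes there were at 0.463-fold and immediate-early genes at 0.605-fold. Summed over these cells there were also macrophage transcripts, Lyz2 at 80.3 CPM, C1qb at 26.1 CPM and Mrc1 at 6.02 CPM, which were nearly absent from SMC-like cells. The cells that carried them were not counted, so a few cells could hold them all. The leading genes of this cluster included Retnla at 143 CPM, Spp1 at 102 CPM and Vcam1, a member of the chemokine and modulated SMC lists, at 1755 CPM, so these ratios cannot be assigned to dividing SMCs. In the 19 cells of cluster 9, chemokine and inflammation genes were 16.5-fold (15.5 to 17.5) and collagens 3.91-fold higher, and contractile genes were at 0.605-fold. The 274 UMIs of Ccl2 in that cluster came from 3 cells.

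The homeobox genes Dlx5 and Dlx6, chosen after their values were seen, set subcluster 5 apart. Dlx5 stood at 110 against 2.30 CPM in the other SMC-like cells, a ratio of 48.0 (40.0 to 57.7), and was seen in 76.1 against 3.15% of cells. Dlx6 stood at 72.2 against 0.824 CPM, a ratio of 87.7 (66.0 to 118), and was seen in 66.4 against 0.989% of cells. The median depths of these groups were 15302 and 17118 UMIs, so the higher shares were not in the deeper cells.

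Of the tests below, those of nuclear RNA in subcluster 2 and of doublets in subcluster 5, with their limits, were set after the values were known. The low contractile and high elastic fibre levels of subcluster 5 were set against technical explanations. Doublets lie between their parts, but the highest elastic fibre level of another subcluster or smaller cluster was 0.747 of its own, at 10511 against 14075 CPM, so mixtures of these groups do not reach it. A few abundant genes do not account for the elastic fibre ratio, which was 1.997 (1.98 to 2.01) with the contractile genes and the 20 most abundant genes left out of the total. Gene length does not either, since the elastic fibre median and sum lay at percentile 100 of 10000 lists matched on level and length while the contractile median lay at percentile 0.520 but its most abundant members had no matched genes of like level. For the elastic fibre level alone, these values are consistent with a distinct state or origin of these SMCs as a hypothesis only, found and tested on the same cells of 1 pool, and no group of the design tests it.

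Subcluster 2 combined low Malat1 with high contractile levels. Uneven depth of sampling does not account for the grouping. With every cell at 5000 UMIs the matching group, at a Jaccard index of 0.621, had a contractile ratio of 1.243 and a Malat1 ratio of 0.186. Thinning keeps the make-up of each cell's RNA, so this test cannot decide whether these cells held less RNA. Less nuclear RNA in these cells stays open, since the summed contractile ratio lay at percentile 99.09 of 10000 draws of genes matched on level and gene length and the median of the members, which went both ways, at 62.4, but the heaviest member, at 23543 CPM, had matched genes with a median of 2012 CPM, so neither value decides. Across 6103 genes, which are not independent, the ratio fell with gene length at a Spearman rho of -0.741, with a median log2 ratio of 0.28 in the shortest 20% and -0.77 in the longest 20% of genes. Against such draws channel genes lay at percentile 57.8 by median and 29.4 by sum, tone receptors, whose 5 members went both ways, at 24.8 and 9.21, both lists within the middle 95%, SMC regulators below nearly all draws by both, at 0.330 by median, and respiration genes at 99.1 and 94.7, and no biological explanation was tested.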
